A study of Escherichia coli BW25113 with 20 samples.

How the data were processed

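Cultures of Escherichia coli BW25113 and of its rsfS deletion strain were grown in shaken M9 minimal medium with glucose, per the labels' protocols. Cells were chilled with chloramphenicol, which holds ribosomes on messages, lysed enzymatically and with detergent, and the lysate was clarified before ribosomes were pelleted through sucrose. Micrococcal nuclease then trimmed the unprotected RNA, and small-RNA libraries were made from the fragments. Clarification removes part of the membrane material, so recovery of ribosomes bound to membranes can vary between preparations, and micrococcal nuclease prefers certain bases, so positions of ribosomes within genes were not analysed here.

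The deposited tables, 1 for each of 14 libraries, give for each of 4354 genes a whole-number count of reads, per the file headers. They also give a deposited RPKM value and a gene length, another quantity used here only to check the RPKM, per the file headers. In each table the RPKM equalled the count divided by the gene length and by the table's total, and RPKM was not used further. The genome build was ASM584v2 and bcl2fastq 2.17 was used for base call conversion, both per the submitters' processing notes. The aligner and the counting tool, how reads at several positions were treated and whether strand was used are not given in the sources used here. Of the gene names, 4230 matched a symbol of the ASM584v2 annotation, 66 matched through 1 synonym and 58 matched none. Of the matched genes 4184 are protein coding and 112 pseudogenes, and 0 genes for ribosomal, transfer or other non-coding RNA are listed, so counts on those RNAs were not analysed here.

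The labels name 20 samples, of which 6 are a second dataset of a library already named. The labels point both datasets to the same table, so each table was taken as 1 library, and how the datasets were combined is not given in the sources used here. The libraries with 2 datasets are both WT 3 h libraries, both ΔrsfS 3 h libraries, ΔrsfS 12 h replicate 2 and ΔrsfS 18 h replicate 1. The groups are WT at 3, 12 and 18 h and ΔrsfS at 3, 12, 18 and 28 h. Total counts were between 568621 and 26978937 per library, and the number of genes with no count was between 60 and 448. ΔrsfS 3 h replicate 1 had the lowest total and ΔrsfS 12 h replicate 2 the most genes with no count.

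Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr over the 7 groups, which left 4179, and libraries were scaled by TMM. A model with 1 mean for each group was fitted to all 14 libraries, with 7 residual degrees of freedom, so that all groups share an estimate of the spread. Quasi-likelihood F tests, which are two-sided, were made for 11 comparisons: the strain effect at 3, 12 and 18 h, 2 steps within WT, 3 steps within ΔrsfS, ΔrsfS at 28 h against WT at 18 h, and the change of the strain effect over 2 intervals. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. The median biological coefficient of variation was 0.313. Standard errors are the log2 fold change divided by the square root of F.

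Of 44 gene lists fixed from general knowledge before the data were examined, 42 were tested with camera from limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated from the data. The other 2 lists, of genes deleted in the parent strain and of structural RNAs, were only described. Which lists are described in a comparison was decided after their tests were seen. The rule for named genes was fixed before the data were examined: in each comparison the 6 largest increases and the 6 largest decreases among called protein-coding genes with at least 50 counts in both libraries of the higher group and no overlap between the replicates of both groups, up to 4 called members with the smallest p of each described list (or 2 where none was called), and rsfS, its neighbours and the hibernation genes in the strain comparisons. For interactions the count minimum applied to any of the 4 groups and overlap was not asked. Fewer were named in places, in the order of the rule. Where a group had no or 1 count, the fold change was given against a floor of 3 counts or with an exact 95% Poisson interval, both of which cover counting error alone. Log2 CPM for correlations and distances used a prior count of 2.

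Alternatives were DESeq2 1.42.0, its size factors in edgeR, total-count scaling, no filter, a filter of 50 counts in 2 libraries, fits on the compared libraries alone, the replicate number as a block, a term for libraries with 2 datasets and leaving out each library in turn. The term for libraries with 2 datasets can be estimated only from ΔrsfS 12 h and ΔrsfS 18 h, whose replicates differ in it. Replicate differences there enter every comparison that the term touches, so fewer calls under it do not show an effect of datasets. Where a library is left out its group keeps 1 library, which is assumed to vary like the other groups. Chosen after seeing the data were thinning each library to 568621 counts, scaling without the 10 most abundant genes of any library, list counts without each library and group distances without each library. A group left with 1 library lies farther from others by construction, so distances were compared only where the WT times kept 2 libraries each. The median over operons of membrane minus soluble log2 fold change was tested by 100000 sign permutations, two-sided, with an interval from 10000 bootstrap draws. Both take operons as units. The operons share the same libraries, so p and interval do not cover the spread between libraries. For the subunits of nuo, atp and sdh alone the draws were of single genes.

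The pipeline was tested on simulated data. Counts were drawn for the real genes and library sizes, from the mean of each gene over all libraries, with 50 genes changed at each fold. Each gene was given the same spread in every group. For the strain effect at 3 h, with 4140 genes in the step, 0 of 50 genes changed by 2-fold were recovered, 31 of 50 at 4-fold, 40 at 8-fold and 44 at 16-fold, with 5 calls among unchanged genes. For the strain effect at 12 h, with 4131 genes, these numbers were 5, 35, 44 and 44, with 8 calls among unchanged genes. For the strain effect at 18 h, with 4137 genes, they were 6, 32, 42 and 49, with 9. The real replicates were not equally spread. Their root mean square log2 difference was 1.03 at WT 3 h, 1.26 at ΔrsfS 3 h and 1.37 at ΔrsfS 12 h. It was 0.534 at WT 12 h, 0.657 at WT 18 h and 0.849 at ΔrsfS 18 h. The simulated numbers therefore hold for equal spread only and do not show how many real calls are false or missed.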

Results

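Ribosome profiling was used to follow which genes were being translated in 2 strains of Escherichia coli during growth in M9 minimal medium with glucose. BW25113 is the K-12 strain from which single-gene deletion collections were built and served as wild type (WT). The other strain, ΔrsfS (dRsfS in the names of comparisons), lacked rsfS, which encodes the ribosome silencing factor, a protein that binds the large ribosomal subunit and hinders its joining with the small one. WT was sampled at 3, 12 and 18 h and ΔrsfS at 3, 12, 18 and 28 h, with 2 libraries in each of the 7 groups. The counts are of footprints, the messenger fragments that ribosomes protect from nuclease, so they combine the amount of a transcript with how densely it was occupied. The series title places the work in the adaptation of bacteria to a lack of nutrients. RNA-seq was not used here, and translational efficiency was therefore not computed. Total counts ranged from 568621 in ΔrsfS 3 h replicate 1 to 26978937 in ΔrsfS 28 h replicate 2. The labels do not say whether the replicates were separate cultures, so the spread behind the p-values may be technical. That spread was estimated over the replicates of all 7 groups together. The p-values may thus be too small where replicates were less alike and too large where they were more alike. Adjusted p-values for genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 4179 genes, and levels are given as CPM, counts relative to the TMM-scaled library total, as mean ± SD of 2 libraries unless another n is stated.

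The deleted gene was examined first because it checks the strain labels. rsfS (b0637) lies at 668719 to 669036 of the ASM584v2 chromosome and is a protein-coding gene. Its footprints came to 148 ± 16.1 CPM (SD, n = 6) in WT and 8.87 ± 1.55 CPM (SD, n = 8) in ΔrsfS, 6.00% of the WT mean. The WT libraries lay between 126 and 162 CPM and the ΔrsfS libraries between 6.17 and 10.6 CPM, so no library of one strain reached the range of the other. The log2 fold change was -4.00 (SE 0.37, adjusted p = 6.25e-05) at 3 h, -4.04 (SE 0.35, adjusted p = 4.23e-05) at 12 h and -3.86 (SE 0.33, adjusted p = 3.81e-05) at 18 h.

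**Figure D1:**
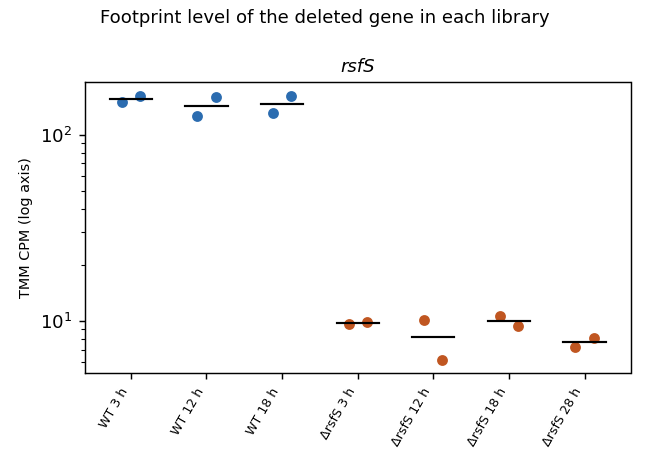
TMM-scaled CPM of rsfS (log axis) for the 7 groups of strain and time on the x axis. Points are single libraries and horizontal lines are group means. The WT libraries lie between 126 and 162 CPM and the ΔrsfS libraries between 6.17 and 10.6 CPM.

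Replicates were not equally alike. Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.981 between the WT 12 h libraries, 0.972 at WT 18 h and 0.981 at ΔrsfS 28 h, but 0.926 at WT 3 h, 0.901 at ΔrsfS 3 h, 0.895 at ΔrsfS 12 h and 0.947 at ΔrsfS 18 h. Each of the 4 libraries taken at 3 h was closer to a library of another group than to its own replicate, and so was ΔrsfS 12 h replicate 1. The counts within each pair differed by more than read-counting error, so no pair was taken as the same library deposited repeatedly. That test covers counting error only and does not show that the replicates were independent.

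The first comparison asked how the strains differed after 3 h. Acid resistance genes had the largest increases in ΔrsfS, and flagellar genes had much lower footprint levels. gadB and gadA, the near-identical glutamate decarboxylases, were 86.5-fold and 67.8-fold higher, and reads from one can be assigned to the other. The acid chaperone gene hdeA was 68.2-fold higher (2238 ± 2300 CPM against 33.4 ± 16.7), and gadE, the regulator of the system, 61.4-fold higher. hdeD and hdeB followed at 39.2-fold and 27.4-fold. Among the genes with lower levels were yjcZ (log2 fold change -5.74, SE 0.72), ves (-5.48, SE 0.49), the phosphodiesterase gene pdeH (-5.38, SE 0.80), the flagellar brake gene ycgR (-4.92, SE 0.56), the basal body gene fliE (-4.79, SE 0.48) and flxA (-4.76, SE 0.49). All 12 had adjusted p of 0.00578 or lower. In all, 154 genes were higher and 104 lower in ΔrsfS.

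Of the 14 acid resistance genes, 13 were higher and none was lower (13 adjusted over the list alone), among them the antiporter gene gadC at 273 against 24.6 CPM. The list stood apart from the other genes (camera adjusted p = 6.07e-23, and adjusted p = 0.0635 with an estimated correlation). General stress genes that depend on the sigma factor RpoS were higher for 22 of 37 and lower for none (32 adjusted over the list alone, camera adjusted p = 5.96e-25, adjusted p = 0.197 with an estimated correlation). Examples were ecnB (log2 fold change 2.89), treA for periplasmic trehalase (2.71), osmY (3.31) and talA (2.66). Of 49 flagellar and chemotaxis genes 27 were lower and none was higher (40 adjusted over the list alone, camera adjusted p = 1.7e-39, adjusted p = 0.197 with an estimated correlation). flgM, flgN and the master regulator gene flhC were at 74.5, 136 and 36.7 CPM against 1459, 2123 and 894 CPM. Among 9 genes for ribosome hibernation and related factors 3 were higher, ygaM (2.53), sra (2.48) and yqjD (1.84), with 5 adjusted over the list alone (camera adjusted p = 0.000163, adjusted p = 0.0635 with an estimated correlation). rmf, the hibernation factor that pairs ribosomes into inactive dimers, had a log2 fold change of 1.18 (SE 0.40, adjusted p = 0.0927), and it passed with DESeq2. Of the 9 genes next to rsfS 1 was higher, nadD (1.48), with 4 adjusted over the list alone (camera adjusted p = 0.0109, adjusted p = 0.573 with an estimated correlation). Of the 25 named genes that passed, 24 kept their calls when any 1 library was left out, and nadD did not. The number of genes called for the strain effect at 3 h fell to 120 without WT replicate 2 and to 151 without ΔrsfS replicate 2, and a fit on these 4 libraries alone called 22, whereas DESeq2 called 509. Without those 2 libraries in turn the flagellar count was 15 and 10 and the RpoS count 9 and 6; it was 44 flagellar genes without ΔrsfS replicate 1 and 13 RpoS genes without WT replicate 1.

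After 12 h the flagellar genes were still lower in ΔrsfS, and genes for the synthesis of histidine, methionine and purines and for iron uptake were lower too. fliC, which encodes flagellin, was at 989 ± 231 CPM in ΔrsfS and 39972 ± 6009 CPM in WT, 40.4-fold apart (adjusted p = 0.000747). ycgR (log2 fold change -5.50), cheY (-5.04), pdeH (-5.01), flgB (-4.94) and fliS (-4.91) completed the 6 largest decreases. The largest increases were led by ybcW and rzoD, which lie in a prophage remnant. ybcW had no counts in either WT library and 273 in ΔrsfS, at least 123-fold higher against a floor of 3 counts over the WT group, and rzoD had 1 count in WT and 499 in ΔrsfS, a ratio of 676 with an exact 95% counting interval of 121 to 26757. rzoD lies wholly inside rzpD, so reads cannot be divided between them. yfcG reached 23041 ± 30114 CPM against 73.6 ± 20.6, and ymgC, ariR and ybeF were 160-fold, 108-fold and 70.5-fold higher. In total 375 genes were higher and 372 lower.

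Of the 49 flagellar genes 46 were lower at 12 h (49 adjusted over the list alone, camera adjusted p = 1.89e-33, adjusted p = 0.249 with an estimated correlation), with log2 fold changes of -4.78 for fliE and -3.49 for flgM. All 8 histidine genes were lower (8 adjusted over the list alone, camera adjusted p = 5.17e-06), including hisA (-2.21) and hisF (-2.47), as were 8 of 12 methionine genes (10 adjusted over the list alone, camera adjusted p = 5.17e-06, and for both lists adjusted p = 0.249 with an estimated correlation), including metN (-2.48) and metB (-1.84). Purine synthesis had 8 of 15 genes lower (10 adjusted over the list alone, camera adjusted p = 6.08e-07), purD by -2.64 and purN by -2.24. Iron and siderophore uptake had 14 of 33 lower (15 adjusted over the list alone, camera adjusted p = 7.77e-08), fecR by -2.58 and fhuC by -2.18. For the purine and iron lists too the adjusted p was 0.249 with an estimated correlation. Toxin-antitoxin genes were higher for 8 of 22 (9 adjusted over the list alone, camera adjusted p = 0.000566, adjusted p = 0.249 with an estimated correlation), with mqsR and mqsA at 3.04 and 3.69. RpoS-dependent genes included 10 higher and 2 lower of 37 (14 and 2 adjusted over the list alone, camera adjusted p = 0.000134, adjusted p = 0.531 with an estimated correlation), with osmB at 3.62 and yjbJ at 4.35. Of the 9 genes next to rsfS 8 were higher (8 adjusted over the list alone, camera adjusted p = 3.72e-05, adjusted p = 0.249 with an estimated correlation), with mrdA for penicillin-binding protein at 2.45 and rlmH for a ribosomal RNA methyltransferase at 1.62. rmf was 6.05-fold higher in ΔrsfS (3172 ± 97.8 against 524 ± 155 CPM, adjusted p = 0.000947), whereas sra (-1.61, adjusted p = 0.0133) and hpf (-1.31, adjusted p = 0.029) were lower, so that 1 of the 9 hibernation genes was higher and 2 were lower (1 and 2 adjusted over the list alone, camera adjusted p = 0.559, adjusted p = 0.736 with an estimated correlation). Over 27 operons that encode both membrane and soluble proteins, the membrane members exceeded the soluble ones by a median log2 value of 0.54. Sign permutation over operons gave p = 0.00098 (adjusted p = 0.0108 over 11 comparisons). Here and below this p covers differences among operons within the same libraries, not between libraries. The operon medians were not repeated with a library left out. With total-count scaling the strain effect at 12 h, with a median of all genes at 0.41, came to 621 genes higher and 203 lower. The calls of sra and hpf ended with it. A term for libraries with 2 datasets left 482 genes called. The count was 251 without WT replicate 1 and 309 without WT replicate 2. Without these libraries the iron count was 7 and 8, the histidine count 3 and 4, the methionine count 3 and 4, the toxin-antitoxin count 2 and 3, the RpoS count 2 and 3 and the neighbour count 2 and 2. Without ΔrsfS replicate 1 there were 9 iron, 3 histidine, 4 methionine, 5 purine and 3 neighbour genes, and without ΔrsfS replicate 2 there were 27 flagellar, 23 iron, 3 toxin-antitoxin and 3 neighbour genes. The flagellar count was 29 and the purine count 5 without WT replicate 1, and the calls of yfcG, sra and hpf ended in at least 1 such fit. Of the hibernation genes 0 were lower without WT replicate 1 and without ΔrsfS replicate 2, where edgeR gave 2 and 2 with an unadjusted p under 0.05.

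By 18 h the direction of the strain difference had turned for flagellar and RpoS-dependent genes. For fliC most of this turn lay in WT, where its log2 fold change from 12 to 18 h was -7.39. Zinc uptake genes, which were high in WT at this time, were far lower in ΔrsfS, and respiratory genes were higher. ykgO and ykgM, which encode zinc-independent paralogs of ribosomal proteins, were at 4.57 ± 3.64 and 6.98 ± 2.23 CPM against 1430 ± 369 and 898 ± 126 CPM in WT, and zinT was at 12.3 ± 3.13 against 2236 ± 719 CPM. tauA for taurine uptake (log2 fold change -5.86), the lysozyme inhibitor gene pliG (-5.47) and thiH for thiamine synthesis (-4.95) were also lower. rzoD had no counts in WT and 667 in ΔrsfS, at least 247-fold higher, and rzpD, ybcW, ymgC and the prophage gene sieB were 87.0-fold, 74.1-fold, 69.5-fold and 57.5-fold higher. rhaD was 61.0-fold higher (76.8 ± 18.2 against 1.34 ± 0.668 CPM), although it belongs to an operon deleted in the parent strain. It also reached 101 CPM in WT 3 h replicate 1. The count was 611 genes higher and 586 lower.

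All 7 genes of the zinc list were lower at 18 h (7 adjusted over the list alone, camera adjusted p = 1.63e-11, adjusted p = 0.0572 with an estimated correlation), with znuC at -3.54 and znuA at -3.88. RpoS-dependent genes were lower for 29 of 37 (33 adjusted over the list alone, camera adjusted p = 1.43e-14, adjusted p = 0.396 with an estimated correlation), including dosP (-3.67) and the trehalose synthesis gene otsB (-2.91). Methionine genes were lower for 11 of 12 (12 adjusted over the list alone, camera adjusted p = 1.14e-10, adjusted p = 0.361 with an estimated correlation), metI by -3.03 and metN by -3.40. Iron uptake had 11 of 33 lower (12 adjusted over the list alone, camera adjusted p = 4.36e-05, adjusted p = 0.45 with an estimated correlation), fecR by -3.80 and fecI by -3.24. All 9 ATP synthase genes were higher (9 adjusted over the list alone, camera adjusted p = 3.96e-08, adjusted p = 0.45 with an estimated correlation), atpI by 3.23 and atpE by 2.87. In the aerobic respiratory chain 18 of 21 were higher, including nuoB (2.47) and nuoK (2.78), and ndh for the alternative NADH dehydrogenase was lower (-2.17), with 20 and 1 adjusted over the list alone (camera adjusted p = 3.96e-08, adjusted p = 0.45 with an estimated correlation). Genes for alternative carbon sources were higher for 22 of 51 (29 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.74e-07, adjusted p = 0.45 with an estimated correlation), mglA for galactose uptake by 4.07 and rbsC for ribose uptake by 2.94. Flagellar genes were higher for 29 of 49 (37 adjusted over the list alone, camera adjusted p = 3.53e-09, adjusted p = 0.477 with an estimated correlation), flgE by 3.69 and flgK by 3.24. Proteins of the large subunit had 13 of 33 genes higher (18 adjusted over the list alone, camera adjusted p = 1.02e-05), rpmH by 2.39 and rpmE by 1.71, and those of the small subunit 9 of 21 (12 adjusted over the list alone, camera adjusted p = 0.000303), rpsS by 2.48 and rpsE by 1.90. With an estimated correlation the adjusted p was 0.477 for both subunits. Of 9 hibernation genes 4 were lower (4 adjusted over the list alone, camera adjusted p = 0.0988, adjusted p = 0.45 with an estimated correlation), ygaM (-2.35), elaB (-4.70), sra (-2.24) and yqjD (-0.83), while rmf was at 0.14 (adjusted p = 0.828). Of the genes next to rsfS 4 of 9 were higher (4 adjusted over the list alone, camera adjusted p = 0.00969, adjusted p = 0.45 with an estimated correlation), mrdA by 2.66 and rlmH by 1.43. The membrane members of the 27 operons exceeded the soluble ones by a median log2 value of 0.47 (permutation p = 0.0124, adjusted p = 0.0341). The number of genes called for the strain effect at 18 h was 642 and 562 without WT replicates 1 and 2 and 686 and 791 without ΔrsfS replicates 1 and 2. Without WT replicates 1 and 2 in turn there were 4 and 1 flagellar, 7 and 7 respiratory, 13 and 11 carbon source, 2 and 2 large-subunit, 1 and 2 small-subunit and 2 and 2 neighbour genes, and 6 iron genes without WT replicate 2. Without ΔrsfS replicate 1 there were 18 RpoS, 7 iron, 7 large-subunit and 2 neighbour genes, and without ΔrsfS replicate 2 there were 1 flagellar, 2 large-subunit and 2 small-subunit genes. The calls of rhaD, tauA, flgK, rpsE and yqjD ended in at least 1 of these fits, and yqjD also lost its call with the DESeq2 size factors and with the filter of 50 counts.

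Whether the strain effect itself differed between times was tested with interaction terms, the change in ΔrsfS minus that in WT. Upward and downward refer to this difference, to which either strain can contribute. The interaction 3 to 12 h was called for 266 genes, 113 upward and 153 downward. All 3 h libraries and ΔrsfS 12 h replicate 2 combine 2 datasets, and a term for this left 119 genes. That term rests on replicate differences at ΔrsfS 12 h and ΔrsfS 18 h, so the drop does not show a dataset effect. A fit on the compared libraries alone called 59 and DESeq2 570. The acid resistance genes hdeA (log2 difference -6.28, adjusted p = 0.0109), gadB (-5.97) and gadA (-5.70), the branched-chain amino acid binding protein gene livJ (-5.91), the arginine uptake gene artJ (-5.58) and argI for arginine synthesis (-5.23) led the decreases. ybcW, rzoD and ymgC (7.14) led the increases; those of ybcW and rzoD have no usable size, since WT at 12 h had 0 and 1 counts. Arginine synthesis had 7 of 11 genes called downward (11 adjusted over the list alone, camera adjusted p = 4.57e-10), argH by -4.38, iron uptake 7 of 33 (16 adjusted over the list alone, camera adjusted p = 4.36e-11), fecR by -2.82 and fepC by -2.42, and acid resistance 5 of 14 (11 adjusted over the list alone, camera adjusted p = 2.28e-07). With an estimated correlation each of the 3 had an adjusted p = 0.269. The membrane members of the 27 operons moved upward against the soluble ones by a median of 0.60 (permutation p = 0.00439, adjusted p = 0.0163). The count of called genes was 161, 21, 70 and 119 without WT 3 h replicate 1, WT 12 h replicate 1, WT 12 h replicate 2 and ΔrsfS 3 h replicate 2, and the calls of 10 of the 12 named genes ended in at least 1 fit, those of argH and fecR excepted. In these 4 fits arginine had 3, 1, 4 and 2 genes called. It had 3 without WT 3 h replicate 2 and 3 without ΔrsfS 12 h replicate 1. Iron uptake had 2, 1, 2 and 16 without WT 3 h replicate 2, WT 12 h replicate 1, WT 12 h replicate 2 and ΔrsfS 12 h replicate 2. Acid resistance had 3, 3, 8 and 2 without WT 3 h replicate 2, WT 12 h replicate 2, ΔrsfS 3 h replicate 1 and ΔrsfS 3 h replicate 2, and edgeR called 0 without WT 12 h replicate 1, with 7 at an unadjusted p under 0.05. Total-count scaling, with a median of all genes at 0.56, called 229 upward and 64 downward, and fepC lost its call with it.

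From the second time to the third, the interaction 12 to 18 h was called for 656 genes, 292 upward and 364 downward. Over this interval 806 genes were called within WT and 82 within ΔrsfS. In WT fliC changed by -7.39 and zinT by 7.48 on the log2 scale, so most of their differences below lay in WT. The soluble ATP synthase subunits averaged -2.71 in WT and 0.77 in ΔrsfS. Flagellar genes moved upward for 47 of 49 (49 adjusted over the list alone, camera adjusted p = 1.13e-45, adjusted p = 0.213 with an estimated correlation), with fliC at 8.30, flgB at 7.75, flgE at 7.68 and fliE at 5.73. All 9 ATP synthase genes moved upward (9 adjusted over the list alone, camera adjusted p = 2.7e-08, adjusted p = 0.291 with an estimated correlation), atpI by 3.03 and atpH by 3.57. RpoS-dependent genes moved downward for 27 of 37 (35 adjusted over the list alone, camera adjusted p = 1.02e-22, adjusted p = 0.2 with an estimated correlation), osmB by -4.55 and otsB by -4.81. Zinc genes moved downward for 6 of 7 (6 adjusted over the list alone, camera adjusted p = 2.84e-11, adjusted p = 0.056 with an estimated correlation), led by ykgO (-9.14), zinT (-8.14), ykgM (-7.29) and znuA (-4.50). tauA had a log2 difference of -7.70 that became 1.15 (adjusted p = 0.744) without ΔrsfS 12 h replicate 2. The count was 328, 370, 434, 323 and 431 without WT 12 h replicate 1, WT 12 h replicate 2, WT 18 h replicate 1, WT 18 h replicate 2 and ΔrsfS 18 h replicate 2. ATP synthase had 5 genes called without WT 18 h replicate 2. Total-count scaling, with a median of all genes at -0.47, called 174 upward and 523 downward.

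**Figure D2:**
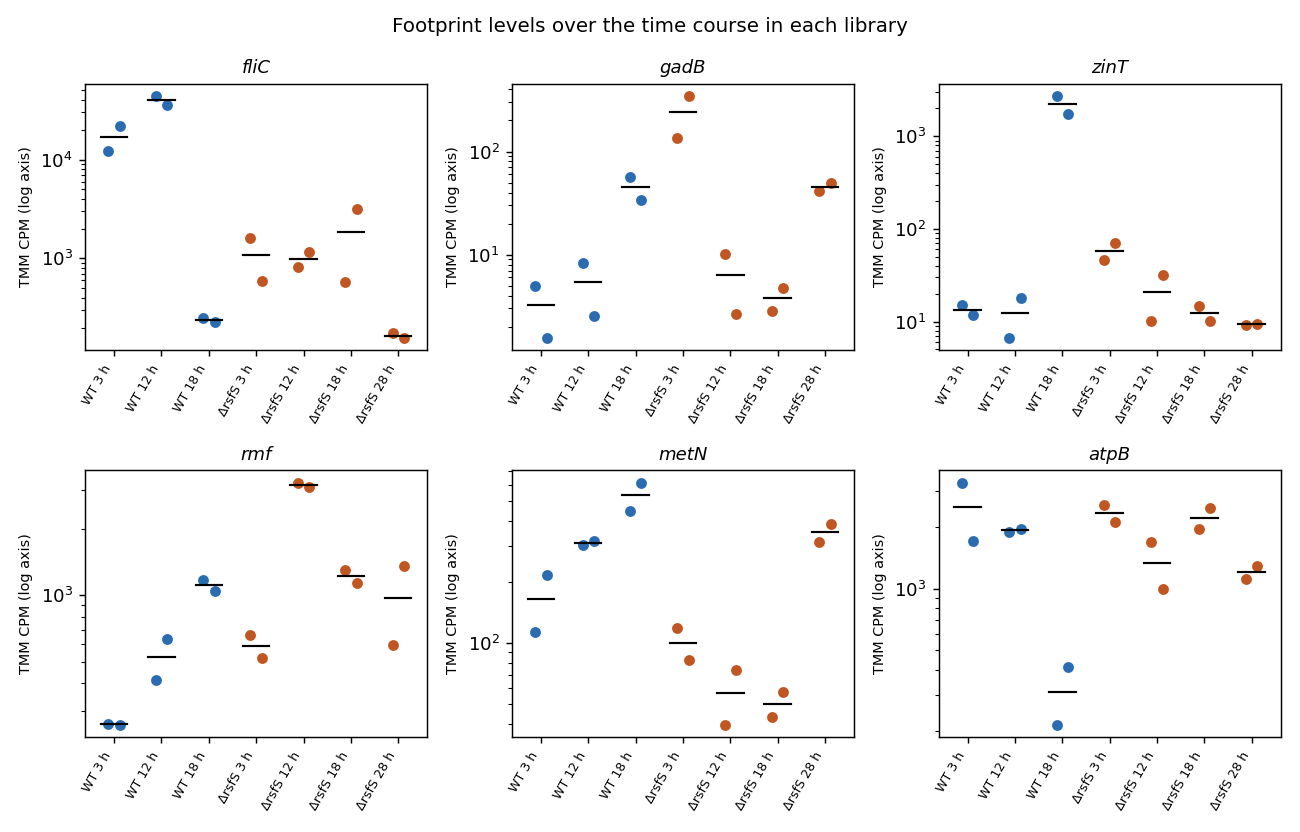
TMM-scaled CPM (log axis) of fliC, gadB, zinT, rmf, metN and atpB for the 7 groups of strain and time; points are single libraries and horizontal lines are group means. fliC fell from 39972 CPM at WT 12 h to 238 CPM at WT 18 h, and zinT was at 2236 CPM at WT 18 h.

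The time course within WT came next. For WT 12 h against 3 h, 88 genes rose and 57 fell. yjjZ (log2 fold change 4.54), ilvC for branched-chain amino acid synthesis (3.96), ybiX (3.95), ybdZ (3.67) and the ribonucleotide reductase genes nrdI (3.65) and nrdF (3.53) rose, and rzoQ (-4.54), rzpQ (-4.40), yhcN (-3.98) and the tyrosine transporter gene tyrP (-3.05) fell, where rzoQ lies inside rzpQ. Iron uptake rose for 10 of 33 (26 adjusted over the list alone, camera adjusted p = 4.5e-23), fecR by 2.53 and fepC by 1.91. Lysine and threonine synthesis rose for 4 of 12 (9 adjusted over the list alone, camera adjusted p = 4.93e-09), lysC by 3.27 and lysA by 2.27, each of these 2 lists with adjusted p = 0.111 with an estimated correlation. Branched-chain synthesis rose for 3 of 14, including ilvE at 1.68 (14 adjusted over the list alone, camera adjusted p = 3.16e-11, adjusted p = 0.171 with an estimated correlation). Both 3 h libraries combine 2 datasets and the 12 h libraries do not, and a term for this left 6 genes called. Within WT the number of datasets coincides with time, and the term rests on replicate differences at ΔrsfS 12 h and ΔrsfS 18 h. The drop therefore does not show a dataset effect. A fit on the compared libraries alone called 31 and DESeq2 414. The count was 49, 8 and 18 without WT 3 h replicate 1, WT 12 h replicate 1 and WT 12 h replicate 2, and ilvC, ybiX, ybdZ, nrdF, rzoQ, rzpQ, yhcN, fepC, lysA and ilvE lost their calls in at least 1 such fit. ybiX also lost it with the DESeq2 size factors, the filter of 50 counts and the replicate number as a block. Iron uptake had 4, 3, 1 and 2 genes called without WT 3 h replicates 1 and 2 and WT 12 h replicates 1 and 2, lysine and threonine 1, 2, 1 and 2, and branched-chain synthesis 1, 0, 0 and 0, where edgeR gave 9, 12 and 9 members with an unadjusted p under 0.05 in the last 3 fits. Total-count scaling, with a median of all genes at -0.38, gave 45 genes higher and 93 lower.

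Between 12 and 18 h in WT, all 49 flagellar genes fell (49 adjusted over the list alone, camera adjusted p = 9.16e-55, adjusted p = 0.191 with an estimated correlation). fliC fell from 39972 ± 6009 to 238 ± 17.6 CPM, flgB, flgC and flgE by -7.82, -7.42 and -7.31 on the log2 scale and fliE by -6.14. Zinc genes rose for 6 of 7 (6 adjusted over the list alone, camera adjusted p = 4.25e-12, adjusted p = 0.0391 with an estimated correlation), zinT by 7.48, ykgO by 7.40, ykgM by 6.58 and znuA by 4.52, and yaiY (5.04), yjfN (4.91) and the pyruvate transporter gene btsT (4.63) rose with them. RpoS-dependent genes rose for 26 of 37 (29 adjusted over the list alone, camera adjusted p = 2.35e-17, adjusted p = 0.21 with an estimated correlation), csiD by 3.55 and otsB by 3.61, and acid resistance genes for 9 of 14 (9 adjusted over the list alone, camera adjusted p = 1.83e-07, adjusted p = 0.243 with an estimated correlation), gadW by 2.98 and gadC by 2.95. All 9 ATP synthase genes fell (9 adjusted over the list alone, camera adjusted p = 2.42e-07, adjusted p = 0.354 with an estimated correlation), atpH by -3.01 and atpB by -2.62. Large-subunit proteins fell for 17 of 33 (24 adjusted over the list alone, camera adjusted p = 2.08e-10, adjusted p = 0.354 with an estimated correlation), rpmE by -2.28 and rpmH by -2.38, and small-subunit proteins for 14 of 21 (16 adjusted over the list alone, camera adjusted p = 1.83e-07, adjusted p = 0.409 with an estimated correlation), rpsT by -2.17 and rpsM by -2.20. In all 410 genes rose and 396 fell for WT 18 h against 12 h, and a fit on the compared libraries alone called 1578. The count was 341 and 386 without WT 12 h replicates 1 and 2 and 433 and 346 without WT 18 h replicates 1 and 2, and the calls of rpsT and rpsM ended in at least 1 of these fits. In that order of libraries there were 6, 4, 2 and 3 large-subunit and 5, 0, 0 and 1 small-subunit genes (14 and 12 with an unadjusted p under 0.05 from edgeR where none was called), with 15 and 16 RpoS genes in the first 2 fits and 4 and 3 ATP synthase genes in the last 2. Acid resistance had 4 genes without WT 12 h replicate 2 and 5 without WT 18 h replicate 1. Total-count scaling, with a median of all genes at 0.54, gave 684 higher and 224 lower.

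In ΔrsfS from 3 to 12 h (dRsfS 12 h against 3 h), 69 genes rose and 67 fell. ymgC (log2 fold change 5.26), rzpD (4.40), rzoD (4.39) and ycgZ (4.03) rose. hdeA (-5.79), gadA (-5.78), artJ (-5.26), gadB (-5.06), argI (-4.85) and hdeB (-4.33) fell. Arginine synthesis fell for 10 of 11 (11 adjusted over the list alone, camera adjusted p = 2e-16, adjusted p = 0.329 with an estimated correlation), argH by -3.32, and acid resistance for 9 of 14 (13 adjusted over the list alone, camera adjusted p = 2e-16, adjusted p = 0.152 with an estimated correlation). The level of argI at 3 h was 2112 ± 2086 CPM. Without ΔrsfS 3 h replicate 2 the count was 12 genes, with 1 arginine and 1 acid resistance gene, and without ΔrsfS 12 h replicate 2 it was 74. Arginine had 4 and acid resistance 5 genes without ΔrsfS 12 h replicate 1, and the calls of ymgC, rzpD, rzoD, gadA, gadB, hdeB and argH ended in at least 1 fit. A fit on these 4 libraries alone called 4 genes and DESeq2 323, and total-count scaling, with a median of all genes at 0.15, gave 73 higher and 32 lower. With the replicate number as a block rzoD lost its call.

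From 12 to 18 h in ΔrsfS (dRsfS 18 h against 12 h), 52 genes rose and 30 fell. The galactarate genes garP (log2 fold change 5.84), garD (5.25) and garK (4.70), glcD for glycolate use (4.01), ykgF (3.81) and the nitrate reductase gene narG (3.40) rose, and the sensor kinase gene phoQ (-3.43) and yhcG (-3.10) fell. Alternative carbon source genes rose for 5 of 51 (14 higher and 1 lower adjusted over the list alone, camera adjusted p = 4.32e-10), rbsC by 3.06 and rbsK by 1.33, and RpoS-dependent genes fell for 6 of 37 (10 adjusted over the list alone, camera adjusted p = 1.02e-09), ecnB by -1.82 and kbp by -2.05. Both lists had an adjusted p = 0.652 with an estimated correlation. The count was 168, 4, 1 and 10 without ΔrsfS 12 h replicates 1 and 2 and ΔrsfS 18 h replicates 1 and 2. In that order there were 9, 1, 1 and 1 carbon source and 3, 0, 0 and 0 RpoS genes (12, 11 and 11 with an unadjusted p under 0.05 from edgeR where none was called), and rbsC was the named gene whose call held in each. rbsK lost its call with total-count scaling, which called 45 genes. Thinning left 51, a fit on the compared libraries alone 13, and DESeq2 called 247.

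From 18 to 28 h in ΔrsfS (dRsfS 28 h against 18 h), 405 genes rose and 431 fell. The biotin synthesis genes bioC (log2 fold change 4.68), bioF (4.36) and bioA (4.28) rose with yjjZ (4.61) and fes (4.42), which encodes the esterase that frees iron from enterobactin. tnaC (-7.51), garP (-7.36), garL (-6.58), rzoD (-6.51), tnaB for tryptophan uptake (-6.48) and treC for trehalose use (-6.36) fell. Iron uptake rose for 23 of 33 (25 adjusted over the list alone, camera adjusted p = 5.29e-14), fecR by 3.02 and fhuF by 2.80, methionine for 11 of 12 (12 adjusted over the list alone, camera adjusted p = 4.77e-11), metI by 2.46 and metN by 2.80, and aromatic amino acid synthesis for 13 of 18 (16 adjusted over the list alone, camera adjusted p = 3.66e-07), aroH by 2.11 and tyrB by 2.02. These 3 lists had an adjusted p = 0.329 with an estimated correlation. Purine synthesis rose for 10 of 15 (15 adjusted over the list alone, camera adjusted p = 1.83e-07, adjusted p = 0.33 with an estimated correlation), purD by 1.95 and purF by 2.20. Flagellar genes fell for 36 of 49 (45 adjusted over the list alone, camera adjusted p = 1.41e-17, adjusted p = 0.33 with an estimated correlation), fliA by -3.76 and flgC by -3.67. Carbon source genes fell for 27 of 51 and 1 rose (32 and 1 adjusted over the list alone, camera adjusted p = 1.95e-15, adjusted p = 0.329 with an estimated correlation), mglA by -3.48 and rbsC by -2.89, and anaerobic genes fell for 18 of 38 (23 lower and 1 higher adjusted over the list alone, camera adjusted p = 6.64e-07, adjusted p = 0.33 with an estimated correlation), narG by -5.26 and narH by -4.13. The membrane members of the 27 operons fell against the soluble ones, with a median log2 value of -0.53 (permutation p = 0.00445, adjusted p = 0.0163). The count was 331 and 489 without ΔrsfS 18 h replicates 1 and 2 and 500 and 235 without ΔrsfS 28 h replicates 1 and 2, and the calls of treC, tyrB and flgC ended in at least 1 of these fits. Without ΔrsfS 18 h replicate 1 there were 7 iron, 6 methionine, 2 aromatic and 3 purine genes, and without ΔrsfS 18 h replicate 2 there were 3 purine, 6 flagellar and 9 anaerobic genes. Without ΔrsfS 28 h replicate 1 there were 15 iron, 5 aromatic, 8 flagellar, 17 carbon source and 9 anaerobic genes, and without replicate 2 there were 13, 8, 3, 12 and 8, with 7 methionine and 4 purine genes. Total-count scaling, with a median of all genes at -0.27, gave 187 higher and 550 lower.

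The last times of both strains, 28 h for ΔrsfS and 18 h for WT, differ in strain and in time (dRsfS 28 h against WT 18 h). Here 231 genes were higher and 218 lower in ΔrsfS. The pyrimidine genes pyrB (log2 fold change 6.73), pyrI (5.76) and pyrL (4.65) and thrC for threonine synthesis (4.71) were higher, and ykgO (-8.82), ykgM (-8.11), zinT (-7.89) and pliG (-4.84) lower. Zinc genes were lower for 6 of 7 (7 adjusted over the list alone, camera adjusted p = 1.25e-20, adjusted p = 0.00782 with an estimated correlation), znuA by -4.53. RpoS-dependent genes were lower for 12 of 37 (19 adjusted over the list alone, camera adjusted p = 2.85e-07, adjusted p = 0.323 with an estimated correlation), osmB by -2.34 and csiD by -1.96. Large-subunit proteins were higher for 18 of 33 (28 adjusted over the list alone, camera adjusted p = 3.86e-13, adjusted p = 0.323 with an estimated correlation), rplV by 3.24 and rplR by 2.06, small-subunit proteins for 11 of 21 (18 adjusted over the list alone, camera adjusted p = 8.86e-10, adjusted p = 0.334 with an estimated correlation), rpsM by 2.52 and rpsO by 2.06, and all 9 ATP synthase genes (9 adjusted over the list alone, camera adjusted p = 4.89e-09, adjusted p = 0.284 with an estimated correlation), atpH by 2.79 and atpC by 4.22. The count was 192 and 86 without WT replicates 1 and 2 and 284 and 100 without ΔrsfS replicates 1 and 2, and the calls of pliG, rplV, rplR, rpsM, rpsO, atpC and csiD ended in at least 1 of these fits. Without either WT library or without ΔrsfS replicate 2 edgeR called 0 large-subunit, 0 small-subunit and 1 ATP synthase gene. Without WT replicate 1, WT replicate 2 and ΔrsfS replicate 2, 18, 21 and 11 large-subunit and 8, 15 and 9 small-subunit genes had an unadjusted p under 0.05. RpoS had 6 and 1 genes without WT replicates 1 and 2 and 4 and 1 without ΔrsfS replicates 1 and 2. Total-count scaling, with a median of all genes at -0.42, gave 111 higher and 334 lower. DESeq2 called 735 and a fit on the compared libraries alone 943.

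The mutant times were also placed against the WT times by the root mean square log2 difference of group means over the 4179 genes. ΔrsfS at 3, 12 and 18 h lay nearest to WT at 3 h, at 1.10, 1.21 and 1.05, and ΔrsfS at 28 h lay nearest to WT at 18 h, at 0.994, with WT at 12 h at 1.02. Single replicate libraries lay 0.528 apart at ΔrsfS 28 h, 0.849 at ΔrsfS 18 h, 1.26 at ΔrsfS 3 h and 1.37 at ΔrsfS 12 h. Averaging over 2 libraries shortens distances, so those between group means cannot be set against these. With 1 ΔrsfS library left out, so that each WT time kept 2, ΔrsfS at 3, 12 and 18 h stayed nearest to WT at 3 h, and ΔrsfS at 28 h lay nearest to WT at 12 h without replicate 1 (1.08 against 1.10 for WT at 18 h). Between single libraries, ΔrsfS 3 h replicate 2 lay nearest to those of WT 18 h (1.23 and 1.24) and farthest from those of WT 3 h (1.28 and 1.29).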

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

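Of the tests in this part, those of the soluble and membrane subunits, of the other membrane operons, of list medians against all genes, of scaling without the most abundant genes, of thinning to equal depth and of rsfS against swapped strain labels were chosen only after the result was seen.

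The genes below stand out because the strain effect differed between times by an interaction test. From 3 to 12 h it differed for 266 genes and from 12 to 18 h for 656. As given above, the first number was much lower with a term for libraries with 2 datasets and on the compared libraries alone. Both numbers changed with single libraries left out, so the values below hold for the main fit only. From 3 to 12 h the log2 difference (edgeR's quasi-likelihood test, adjusted p between 0.0044 and 0.0478) was -5.97 for gadB, -6.28 for hdeA, -5.70 for gadA, -4.41 for gadE, -4.17 for hdeB, -2.56 for talA, -2.65 for ygaM and -4.09 for sra. It was -2.42 for hisA, -2.55 for hisF, -2.21 for metB, -2.35 for purD and -2.82 for fecR. The fitted values of 10.20 for ybcW and 9.32 for rzoD depend on the prior count, because WT at 12 h had 0 and 1 counts. It was 2.355 for ves, 7.14 for ymgC, 4.73 for ariR, 5.13 for ybeF, 2.80 for mqsR, 2.86 for mqsA, 2.02 for mrdA and 2.44 for osmB.

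From 12 to 18 h (adjusted p between 6.9e-05 and 0.0446) it was 7.58 for ycgR, 8.30 for fliC, 5.835 for cheY, 7.28 for pdeH, 7.75 for flgB, 6.83 for fliS, 5.73 for fliE, 4.48 for flgM, 7.68 for flgE and 7.43 for flgK. It was 2.45 for purD, 2.50 for purN, 3.03 for atpI, 2.73 for atpE, 2.86 for mglA, 5.05 for rbsC, 3.45 for sdhB, 1.74 for sdhD, 2.37 for rpmH, 2.26 for rpmE and 2.56 for rpsS. Downward differences were -6.67 for yfcG, -3.09 for mqsR, -3.51 for mqsA, -4.55 for osmB, -4.09 for yjbJ, -2.46 for rmf, -9.14 for ykgO, -8.14 for zinT, -7.29 for ykgM, -7.70 for tauA, -5.61 for pliG, -4.05 for thiH, -3.31 for znuC and -4.50 for znuA. Further ones were -2.37 for dosP, -4.81 for otsB, -1.87 for fecI, -2.22 for ygaM, -4.56 for elaB and -1.41 for yqjD. The difference of tauA changed sign without ΔrsfS 12 h replicate 2. That of yfcG rests on a level of 23041 ± 30114 CPM in ΔrsfS at 12 h.

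rhaD belongs to an operon deleted in the parent strain and still had up to 514 counts in a library, ΔrsfS 18 h replicate 2. Its level differed between replicates at 3 h, with 101 and 2.16 CPM in WT and 231 and 8.42 CPM in ΔrsfS. At ΔrsfS 28 h it was 1.30 and 1.40 CPM, so high levels were neither limited to ΔrsfS nor found in all its libraries. rhaA and rhaB of the same operon had at most 4 counts in any library, and 0 in ΔrsfS 18 h replicate 2. The deleted genes araA, araB and araD had at most 9. High counts on rhaD thus came with few or none on the other deleted genes, and the cause was not tested.

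Respiratory chain and ATP synthase genes were higher in ΔrsfS at 18 h, although neither list passed with an estimated correlation. The tables argue against uneven recovery of ribosomes on the reading frames of membrane proteins as the whole of it, because the soluble subunits of nuo, atp and sdh had a median log2 fold change of 2.50 (13 genes, lower quartile 2.38). The membrane subunits (12 genes, median 2.59) exceeded the soluble ones by only 0.0876, with 0.12 for nuo, 0.14 for atp and -0.38 for sdh. These values lie below 0.5, which goes against such recovery as a part of that size, as far as 3 operons can show. The bootstrap interval (-0.18 to 0.31) resampled single genes of these operons, which are not independent, so it is too narrow to decide this. The tables argue against a wrong scaling as the source of the excess of these lists over other genes. Such a scaling shifts all genes alike, so by construction it leaves that excess unchanged. Absolute levels are not decided by this. The lower of the medians of both lists exceeded the median of all genes by 2.52, and the lower quartile by 2.07. Other scalings decide nothing, since total-count scaling and scaling without the most abundant genes moved the list medians by at most 0.0727, to 2.38 at the lowest. Uneven recovery of whole messages held at the membrane stays open, since the soluble subunits share messages with the membrane ones. The membrane members of the other 24 operons had a median of 1.62 (quartiles 0.28 and 2.65) and were lower in 6. This lies between the bounds for either answer, which were set after the result was seen. The excess of membrane over soluble members over all 27 operons (0.47, bootstrap interval 0.12 to 1.05) also lies between its bounds. The strain difference that the design names also stays open.

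The 3 h replicates were less alike than those of WT 12 h, WT 18 h and ΔrsfS 28 h, while the ΔrsfS 12 h replicates were the least alike of all groups. Against the mean of those 3 groups, the most alike ones, the mean correlation of both 3 h groups was lower as deposited (difference -0.0645) and by less at equal depth (difference -0.0420). Counting depth therefore does not account for the whole gap, although part of it went with depth. At equal depth r was 0.925 at WT 3 h, 0.923 at ΔrsfS 3 h, 0.919 at ΔrsfS 12 h and 0.946 at ΔrsfS 18 h, so low similarity was not limited to 3 h. Each of these groups holds a library with 2 datasets, and WT 12 h, WT 18 h and ΔrsfS 28 h hold none. Whether this accounts for the lower similarity was not tested. Swapped strain labels are excluded by rsfS, with the lowest WT level 11.9 times the highest ΔrsfS level. Pairing the ΔrsfS 3 h and 12 h libraries as labelled gave a mean correlation higher by 0.0113 than the better crossed pairing, which goes against a swap of these labels by a small margin. A difference in growth state between cultures was not tested.

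Of the 9 genes next to rsfS, 1 (nadD) was called higher in ΔrsfS at 3 h, 8 at 12 h and 4 at 18 h, and cobC had a log2 fold change of -0.29 at 18 h. At 3 h camera gave an adjusted p = 0.0109, and 0.573 with an estimated correlation, and the call of nadD ended without either WT library and without ΔrsfS replicate 1, and also with total-count scaling, the filter of 50 counts and the replicate number as a block. With a library left out, 2 or 3 genes of this list were called at 12 h and 2 to 4 at 18 h. A local effect of the deletion may contribute, since the median of the 9 neighbours over 3, 12 and 18 h (0.90) lay at percentile 95.6 of windows of 9 consecutive genes. That value is just inside the bound of the upper 5 percent set beforehand, and the 9 genes beyond the neighbours had medians of 0.86 on one side and 1.52 on the other, so higher levels were not limited to the neighbours. Other explanations were not tested.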

How the results depend on the processing

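Of the alternatives in this part, thinning, scaling without the most abundant genes, list counts without each library and group distances without each library were chosen after seeing the data. Values below are called genes for the comparisons strain effect at 3 h, strain effect at 12 h, strain effect at 18 h, WT 12 h against 3 h, WT 18 h against 12 h, dRsfS 12 h against 3 h, dRsfS 18 h against 12 h, dRsfS 28 h against 18 h, dRsfS 28 h against WT 18 h, interaction 3 to 12 h and interaction 12 to 18 h, and the cause of each move was not tested. With DESeq2 there were 509 for the strain effect at 3 h, 414 for WT 12 against 3 h, 323 for ΔrsfS 12 against 3 h, 247 for ΔrsfS 18 against 12 h, 735 for ΔrsfS 28 h against WT 18 h and 570 for the interaction from 3 to 12 h. With only the compared libraries these were 22, 31, 4, 13, 943 and 59, and WT 18 against 12 h had 1578. With a term for 2 datasets there were 482 for the strain effect at 12 h, 6 for WT 12 against 3 h and 119 for the interaction from 3 to 12 h. ΔrsfS 18 against 12 h had 45 with total-count scaling and 51 after thinning. Leaving out a library gave 120 to 293 for the strain effect at 3 h, 251 to 654 at 12 h and 562 to 791 at 18 h; 8 to 127 for WT 12 against 3 h and 341 to 433 for WT 18 against 12 h; 12 to 146, 1 to 168 and 235 to 500 for the ΔrsfS steps; 86 to 284 for ΔrsfS 28 h against WT 18 h; and 21 to 284 and 323 to 710 for the interactions. With the replicate number as a block the called genes were 240, 706 and 1172 for the strain effect at 3, 12 and 18 h. Within WT they were 97 and 771, and within ΔrsfS 103, 75 and 804. There were 373 for ΔrsfS 28 h against WT 18 h and 261 and 626 for the interactions. Deviations of same-numbered libraries correlated over 0.1 for 3 of 21 pairs of groups (-0.29 to 0.20). The highest were ΔrsfS 18 h with ΔrsfS 28 h (0.20) and WT 3 h with ΔrsfS 3 h (0.16). The numbers thus showed no pairing over all groups, but pairing within a time or between neighbouring times cannot be excluded.

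With an estimated correlation 1 gene list, zinc, was called in WT 18 against 12 h and 1, zinc, in ΔrsfS 28 h against WT 18 h, and 0 in each of the other 9 comparisons, against 6 to 26 with the preset one. Leaving out a library gave 10 to 22 lists for the strain effect at 3 h and 4 to 12 for ΔrsfS 18 against 12 h. Of 228 named calls 168 held whichever library was left out, and 1 reversed (tauA log2 fold change: interaction 12 to 18 h), at 1.15 without ΔrsfS 12 h replicate 2 and at lowest -9.31 without ΔrsfS 18 h replicate 2. Removal of structural RNAs was not run because none are listed. What depth limits was examined by thinning alone. The lowest total was that of ΔrsfS 3 h replicate 1 (568621, with 355 genes at no count), and ΔrsfS 12 h replicate 2 had the most genes at no count (448).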

Other observations

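Of the tests in this part, the correlations between steps of both strains, the count of lists shared by both steps and the list counts without each library were chosen only after the results were seen, and so was which lists to describe.

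Peptide and amino acid uptake genes were higher in ΔrsfS at 28 h than in WT at 18 h for 15 of 30 (21 adjusted over the list alone, camera adjusted p = 7.42e-14, adjusted p = 0.141 with an estimated correlation). oppB of the oligopeptide transporter was at 1262 ± 409 CPM against 113 ± 8.46 CPM and gltJ for glutamate uptake at 137 ± 5.67 against 34.2 ± 0.145 CPM (SD, 2 libraries per group). The list had 8, 7 and 8 genes called without WT 18 h replicate 1, WT 18 h replicate 2 and ΔrsfS 28 h replicate 2. Genes of the tricarboxylic acid cycle were higher in ΔrsfS at 18 h for 8 of 18 (8 adjusted over the list alone, camera adjusted p = 0.000572, adjusted p = 0.45 with an estimated correlation), with log2 fold changes of 2.68 for sdhB and 2.51 for sdhD, and 5 genes were called without WT 18 h replicate 2.

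A hypothesis was that ΔrsfS goes through the changes of WT later. Across 4179 genes, which are not independent replicates, the log2 fold changes of ΔrsfS from 18 to 28 h correlated with those of WT from 3 to 12 h (Pearson's r = 0.539, Spearman's rho = 0.541) and hardly with those of WT from 12 to 18 h (r = 0.1195, rho = 0.0674). The comparisons share no libraries. Both WT 3 h libraries and ΔrsfS 18 h replicate 1 combine 2 datasets, whereas the WT 12 h and ΔrsfS 28 h libraries do not. A difference between datasets could therefore enter both steps. A term for it left 6 of 145 genes called in the WT step, where the number of datasets coincides with time. The term was estimated from replicate differences at ΔrsfS 12 h and ΔrsfS 18 h, so it cannot decide whether datasets differed. WT 3 h replicate 1 was closer to ΔrsfS 18 h replicate 2 (r = 0.932) than to its own replicate (r = 0.926). The correlation between the steps was not repeated with a library left out. Of 6 pairs of steps between the strains the other 4 had r between -0.205 and 0.0429. The value of 0.539 goes with a delay of the earlier step as far as a correlation can, within these limits. That of 0.1195 lies between the bounds for either answer. The bounds for both correlations were set after the results were seen. By distance of group means, ΔrsfS at 18 h lay nearest to WT at 3 h (1.05), as a delay of the earlier step would have it. ΔrsfS at 28 h lay nearest to WT at 18 h (0.994) and not to WT at 12 h (1.02), as it would not. That margin was small and turned without ΔrsfS 28 h replicate 1. Of 42 gene lists 15 had a camera adjusted p under 0.05 in both steps, 14 in the same direction. Among these 14, those with 3 or more genes called upward in WT 12 h against 3 h were iron uptake (10 of 33, and 23 in the ΔrsfS step), oxidative stress (7 of 20, and 7), lysine and threonine (4 of 12, and 7), and branched-chain (3 of 14, and 8), methionine (3 of 12, and 11) and aromatic synthesis (3 of 18, and 13). These counts were fragile. With a library left out the WT step had 1 to 4 iron and 1 or 2 lysine and threonine genes. edgeR called 0 methionine genes in each such fit (6 to 8 with an unadjusted p under 0.05), and 0 branched-chain genes in 3 of the 4 fits (9 to 12 with an unadjusted p under 0.05). Without WT 12 h replicate 1 edgeR called 0 oxidative stress and 0 aromatic genes upward (9 and 5 with an unadjusted p under 0.05). The lowest such counts of the ΔrsfS step were 7, 4, 1, 4, 6 and 2 in the order of the lists above. With an estimated correlation every list had an adjusted p of 0.111 or more in the WT step and 0.329 or more in the ΔrsfS step. Another 4 lists passed with the preset correlation in the WT step alone and 9 in the ΔrsfS step alone, and flagellar genes went in opposite directions. They fell for 36 of 49 in the ΔrsfS step (median log2 fold change -2.70), where edgeR called 0 in the WT step (median 0.70, 5 higher with an unadjusted p under 0.05). Carbon source genes fell for 27 of 51 against 0 (1 higher and 2 lower with an unadjusted p under 0.05 from edgeR), and purine genes rose for 10 of 15 against 0 (1 higher with an unadjusted p under 0.05 from edgeR). The ΔrsfS step thus held calls that the WT step did not. A shared difference in preparation, such as in recovery of membrane-bound ribosomes, was not excluded: the median of membrane minus soluble members of operons was -0.53 in the ΔrsfS step and -0.17 in the WT step (permutation p = 0.00445 and 0.117).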
